A study of Mus musculus with 4776 samples.

How the data were processed

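The deposited exon and intron tables hold, per the labels and the deposited file headers, 1 read count per gene and cell: 45768 genes over 4776 cells. Another deposited table gives counts of 98 construct parts in 4267 of the cells, with none from ALM. Per the submitters' processing notes, reads were aligned with STAR 2.5.3 to GRCm38 (mm10). Read trimming, duplicate handling and the counting of reads that match several genes are not given in the sources used here. The number of per-sample value columns left unused is 0. Gene positions came from a GENCODE annotation of the same build. Exon counts were used for all gene comparisons, and intron counts for the intron share and 1 alternative.

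Groups, layers and preparation dates came from the labels. Cells with under 50000 exon reads were left out, a limit chosen after the data were seen, which removed 11 cells and kept 4765. Exon counts were summed per mouse and class (per dissected layer where layers were compared), and a sum needed at least 5 cells. The design, the comparisons, the 32 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

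Sums were fitted with edgeR 4.0.16 (TMM scaling, low-count filter with a minimum count of 10, trended dispersion, robust quasi-likelihood fit and test), with population or mouse as a covariate where the text says so. Tests were two-sided, and p values were Benjamini-Hochberg adjusted over all genes tested, with calls at 0.05. The SE of a fold change is its absolute value divided by the root of the F statistic. The difference between classes was fitted with limma 3.58.1 on the difference within each mouse (prior count 2). Where an arm held 1 mouse, the lone sample was assumed to vary like the other groups. Gene lists were tested with camera at an inter-gene correlation of 0.01 and again with the estimated correlation, adjusted over the 32 lists. DESeq2 1.42.0 and limma-trend served as alternatives.

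Genes were named by rule: up to 8 per direction in main comparisons (6 for layers, 4 for single lines) with a mean of at least 20 CPM in the higher group and every mouse of the smaller group on the called side, plus up to 3 per gene list by smallest p, and the driver genes. Sex-dimorphic genes, pseudogenes and unnamed transcripts were left out of the ranking. Of the genes so picked, the text prints a part, chosen for length after their values were seen. Genes with 0 reads in a group are given as at least N-fold against a floor of 3 reads over that group. Intervals and floors cover counting error only.

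Genes detected were counted after thinning each cell to 200000 exon reads, and the intron share is introns over exons plus introns. Values per mouse were compared by permutation of mice within populations, exactly, or with 100000 resamples where both groups had at least 10 mice. Transgene levels are log2(CPM + 1). Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 1), which gave 43 clusters, of which 36 were named from marker genes fixed beforehand (at least 3 markers above a log2 fold of 1 and 5 CPM, and among the top 10 genes no more markers of another class than of its own, which left 3 clusters with 5 markers unnamed). Software ran under Python 3.11.15 and R 4.3.3.

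A self-test drew counts for the real genes from the fitted means, dispersions and library sizes, with 200 genes changed by known folds. Of 100 genes changed by a log2 fold of 1, edgeR recovered 81 for the pooled TIGRE comparison, 56 for Snap25 glutamatergic cells, 67 for Pvalb against Sst and 3 for Scnn1a; at a fold of 2 it recovered 100, 93, 87 and 36. For the difference between classes limma recovered 0 of 100 at both sizes.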

Results

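Single neurons were sorted from 2 cortical areas of adult mice, the primary visual area (VISp) and the anterior lateral motor area (ALM). Each mouse carried a recombinase driver, which marks a neuron population, and all but 1 group also carried a transgenic reporter of that recombinase. The deposited files hold 4776 cells from 79 mice, 22 female and 57 male, in 17 groups of driver, reporter and area, with 4528 cells from VISp and 248 from ALM. The labels class 2807 cells as glutamatergic and 1969 as GABAergic. The mouse, not the cell, was taken as the replicate.

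The reporters form 2 families. Ai14 expresses red tdTomato, a part also listed for Ai139 and Ai163. Ai139, Ai148, Ai162 and Ai163, the TIGRE family, drive a green protein (EGFP, Ai139) or calcium indicator (GCaMP6, the other 3) through the transactivator tTA2. Pvalb-IRES-Cre mice with Ai14, whose driver marks fast-spiking interneurons, gave 540 VISp cells from 17 mice and 126 ALM cells from 8 mice. The same driver gave 95 cells from 1 mouse with Ai162 and 63 cells from 1 mouse with Ai163. A second Pvalb driver, the tamoxifen-induced Pvalb-T2A-CreERT2, gave 16 VISp cells from 1 mouse with Ai139, 39 cells from 2 mice with the Ai139-hyg version and 70 ALM cells from 3 mice with Ai139. The Sst driver, which marks somatostatin interneurons, gave 370 VISp cells from 3 mice with Ai14 and 63 from 2 mice with Ai14 and Ai148. The Rbp4 driver, used for layer 5 neurons, gave 1120 cells from 14 mice with Ai14 and 87 from 1 mouse with Ai14 and Ai148. The Scnn1a driver, used for layer 4 neurons, gave 129 cells from 1 mouse with Ai14 and 48 from 3 mice with Ai139. Snap25-IRES2-Cre, a driver active in all neurons, gave 1487 VISp cells from 12 mice with Ai14 and 471 cells from 2 mice without a transgenic reporter, sorted on green fluorescence. The labels' protocol names an injected virus that carries a recombinase-dependent EGFP but states the injection for no single mouse.

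A cell had a median of 1607519 exon reads, with a range from 274 to 3526692. Group medians ran from 464865.5 exon reads in Scnn1a mice with Ai139 to 2098820 in ALM mice with Ai139. The TIGRE and green-sorted groups prepared from December 2017 were shallower than their controls: medians were 1072108 exon reads with Ai162, 975240 with Ai163 and 993953 in the glutamatergic cells without a transgenic reporter, against 1817694.5 in Pvalb VISp mice with Ai14 and 1721517 in Snap25 glutamatergic cells with Ai14. Gene comparisons used exon reads summed per mouse. Fold changes are on the log2 scale with their standard error (SE), levels are normalised CPM ± SD, and FDR is the Benjamini-Hochberg adjusted two-sided p of edgeR's quasi-likelihood test unless another test is named. Gene lists were tested with camera at a preset correlation between genes; a camera call given without a second value held with an estimated correlation.

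The transgene transcripts checked the genotype labels. tTA2 averaged 7.93 ± 1.44 on the log2(CPM + 1) scale in TIGRE mice (SD, n = 11 mice with construct counts) and was listed at 0 in the 33 Ai14 mice of the same populations. The difference within populations was 8.01 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). EGFP reached 11.7 ± 0.539 in the 3 VISp Pvalb mice with Ai139 and was listed at 0 in the 16 mice with Ai14 (exact permutation p = 0.00103, the smallest possible). GCaMP6 stood at 11.3 ± 0.439 in 5 mice with Ai148, Ai162 or Ai163 against 2.54 ± 0.604 in 32 Ai14 mice (difference 8.72, exact permutation p = 4.67e-05, the smallest possible). Cells sorted from Snap25 mice without a transgenic reporter had EGFP at 11.5 in glutamatergic cells of 2 mice against 0 in 4 Ai14 mice, while tdTomato was lower by a log2 difference of -7.20; the exact permutation p was 0.0667 for each, the smallest that this design allows. In their GABAergic cells, with 1 mouse against 12, EGFP stood at 12.3 and the tdTomato difference was -6.61, each with an exact permutation p of 0.0769, again the smallest allowed.

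Reporter levels varied among TIGRE mice. tTA2 averaged 1172 CPM in the Ai162 mouse, 1042 CPM in the Rbp4 mouse with Ai148 and 97.5 CPM in the Ai163 mouse. EGFP averaged 26280 ± 1363 CPM in Scnn1a mice with Ai139 (n = 3). GCaMP6 ran from 2670 ± 124.1 CPM in Sst mice (n = 2) to 6915 CPM in the Rbp4 mouse, both with Ai148. tdTomato averaged between 85.3 CPM in Sst mice and 174.8 CPM in Snap25 glutamatergic cells among mice with Ai14 alone.

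The first comparison asks what a TIGRE reporter changes in the neurons that carry it, beside neurons of the same population with Ai14 alone. Across 5 populations, 14 TIGRE mice were set against 38 Ai14 mice with the population as a covariate. In 6 of the 14, Pvalb mice with Ai139, the driver was Pvalb-T2A-CreERT2 while their controls had Pvalb-IRES-Cre. Driver, tamoxifen induction and reporter differ together there. Among the genes picked by the naming rule, Gpr56, an adhesion receptor, was higher by 2.91 (SE 0.265, FDR = 3.33e-11), at 45.3 ± 24.9 CPM against 6.69 ± 4.16 CPM (SD). Gstm5, a glutathione transferase, was higher by 1.91 (SE 0.123, FDR = 1.84e-16), at 833.2 ± 402.9 against 204.8 ± 54.1 CPM. Prdx1, a peroxiredoxin that removes peroxides, rose by 1.80 (SE 0.116, FDR = 1.84e-16), from 161.4 ± 80.8 to 501.4 ± 284.5 CPM, and Pea15a, a phosphoprotein with a death effector domain, rose from 472.8 ± 147.2 to 1053 ± 220.1 CPM (FDR = 5.06e-14). All 4 genes stood above the Ai14 mean of their population in 14 of 14 TIGRE mice. The calcium-binding protein Cib2 rose by 0.93 (FDR = 8.08e-06), the phosphatase Ubash3b by 1.07 (FDR = 0.00176) and Pclo, a scaffold of the presynaptic active zone, by 0.59 (FDR = 1.07e-05, 10 of 14 mice).

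**Figure D1:**
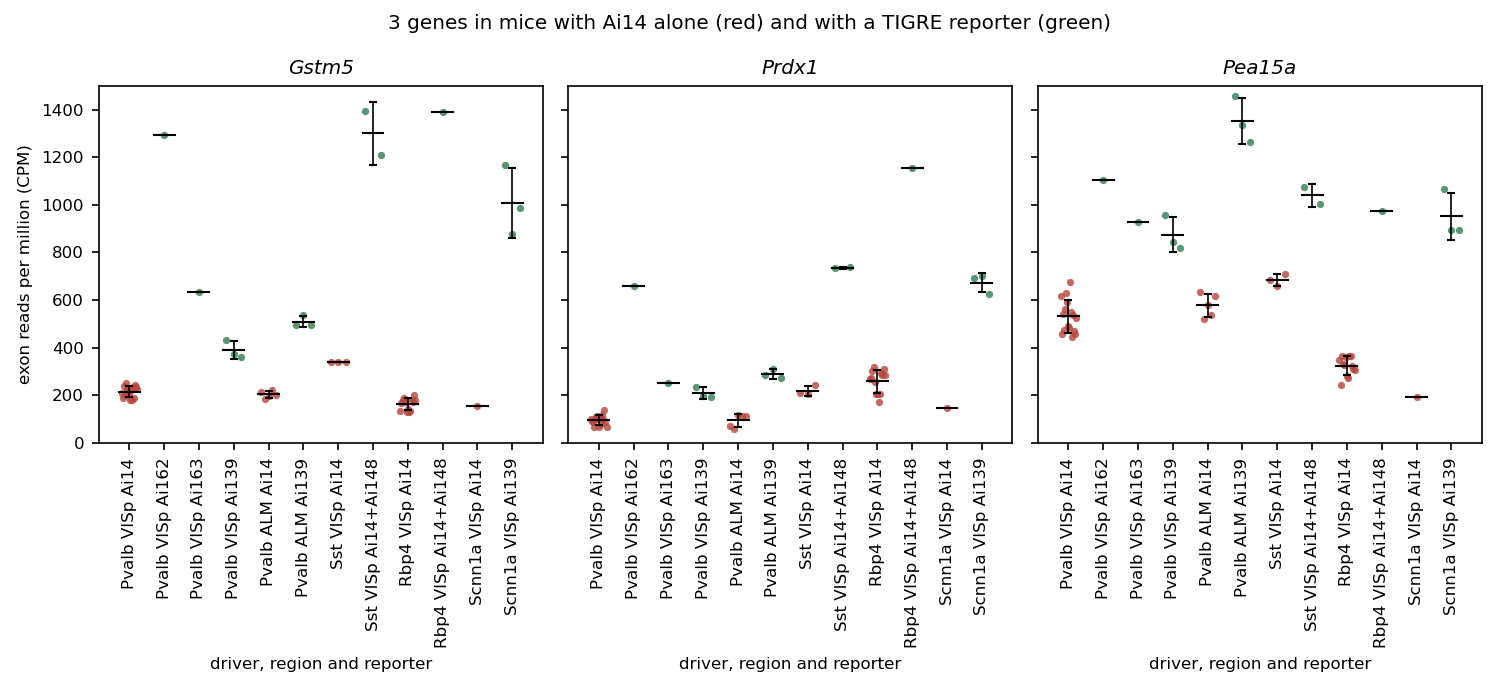
Level of Gstm5, Prdx1 and Pea15a in CPM, 1 point per mouse, for Ai14 mice (red) and TIGRE mice (green) of each population; black lines are group means and error bars SD. Gstm5 averaged 204.8 CPM in the 38 Ai14 mice and 833.2 CPM in the 14 TIGRE mice.

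Of 24360 genes tested between TIGRE and Ai14 mice, 1341 passed an adjusted p of 0.05, 712 higher and 629 lower (limma-trend called 3770, 423 higher and 3347 lower). The raised genes included the protein machinery. Of 42 cytosolic ribosomal protein genes, 8 rose and 0 fell over all genes tested, and 29 rose adjusted over the list alone (median 0.23). Rps20 rose by 0.34 (FDR = 0.0102) and Rpl7 by 0.29 (FDR = 0.0182). The list's camera FDR was 1.47e-21 with the preset correlation and adjusted p = 0.142 with an estimated correlation. Of 25 proteasome and ubiquitin genes, 14 rose and 0 fell, 19 adjusted over the list alone (median 0.19, camera FDR = 3.45e-20). Among them, the ubiquitin gene Ubb rose by 0.36 (FDR = 2.06e-05, 1433 ± 212.8 against 1077 ± 138.8 CPM), Psmb3 by 0.30 (FDR = 0.000736) and Psmc1 by 0.27 (FDR = 6.29e-05). Of 37 oxidative phosphorylation genes, 16 rose and 0 fell, 25 adjusted over the list alone, with Cox7a2 at 0.40 (FDR = 0.00875), Ndufa4 at 0.36 (FDR = 0.0137) and Sdhd at 0.25 (FDR = 0.0144). That list's camera FDR was 1.22e-19, and adjusted p = 0.061 with an estimated correlation.

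Lower genes included ion channels and receptors. Of 29 potassium and sodium channel genes, 7 fell and 0 rose, with 11 lower and 1 higher adjusted over the list alone (median -0.31, camera FDR = 4.81e-06). The potassium channel subunits Kcnab1 (-0.76, FDR = 0.00015, 14 of 14 mice), Kcnh7 (-0.60, FDR = 0.00031) and Kcna1 (-0.53, FDR = 0.0023) fell, as did the sodium channel Scn8a (-0.34, FDR = 0.00681). Of 26 glutamate receptor and postsynaptic genes, 8 fell and 0 rose, 9 adjusted over the list alone (median -0.29, camera FDR = 8.1e-06). They included the receptor subunits Grm5 (-0.32, FDR = 0.00722), Gria1 (-0.35, FDR = 0.0286) and Gria2 (-0.21, FDR = 0.0278). Of 20 GABA synthesis and receptor genes, 2 fell, the receptor subunits Gabrb2 (-0.31, FDR = 0.016) and Gabrg3 (-0.44, FDR = 0.0233), and 9 fell adjusted over the list alone (camera FDR = 0.00025). The chaperone Hsph1 fell by 0.39 (FDR = 0.000445, 14 of 14 mice), the chromatin protein Setd5 by 0.78 (FDR = 5.11e-05) and Neto2, an auxiliary subunit of kainate receptors, by 0.89 (FDR = 0.0271). Without the first ALM mouse with Ai139 the Gria2 call was lost, and without the first Sst mouse with Ai148 the Gria1 call was lost.

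Of 18 Pvalb interneuron markers, 2 fell, with 7 lower and 1 higher adjusted over the list alone (camera FDR = 0.007). Of 29 synaptic vesicle genes, 4 fell and 1 rose, 9 and 2 adjusted over the list alone (camera FDR = 0.0154, adjusted p = 0.232 with an estimated correlation): Pclo rose, while the active zone genes Bsn (-0.37, FDR = 0.0228) and Rims1 (-0.55, FDR = 0.0223) fell. In the MHC class I antigen presentation list, the proteasome activators Psme1 (0.31, FDR = 0.0208) and Psme2 (0.31, FDR = 0.0138) were the 2 of 14 genes that rose, 3 adjusted over the list alone; the list's median was 0.03, its mean -0.05 and its direction upward (camera FDR = 0.0408, adjusted p = 0.128 with an estimated correlation). Of the 11 lists called in all, 5 held with an estimated correlation.

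RNA quality signs moved with the same contrast. At a matched 200000 exon reads per cell, TIGRE mice had 7189 ± 631.2 genes detected against 8295 ± 472.4 in Ai14 mice (SD, n = 14 and 38), a difference of -757.9 genes within populations, lower in 13 of 14 mice (permutation p = 1e-05, the smallest possible). The intron share of reads was 11.3% ± 3.46 against 14.2% ± 4.84, a difference of -3.81 percentage points within populations (permutation p = 0.00013). Among the libraries prepared before December 2017, a restriction chosen after the data were seen, 113 genes passed, 65 higher and 48 lower, of which 83 were also called over all libraries. There, 9 of the 39 genes named for this comparison passed: Gstm5, Prdx1, Pea15a, Gpr56, Cib2, Pclo, Neto2, Kcna1 and Kcnab1. Neto2 and Kcna1 lost their call without the Pvalb-T2A-CreERT2 mice, as did 2 others of the 39, and with only the GCaMP6 reporters, where 13 did, Kcnh7, Scn8a, Gabrb2, Bsn, Rims1, Psme1 and Sdhd among them. With limma-trend Rps20, Psme1 and Psme2 were lost. With period as a covariate 18 of the 39 passed, and within named clusters 23.

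The Pvalb VISp mice allow single TIGRE lines to be set against 16 Ai14 mice, with the lone sample of a line assumed to vary like the other groups. In the Ai162 mouse, Gstm5 was higher by 2.65 (SE 0.122, FDR = 1.2e-11), at 1352 CPM against 215.2 ± 22.9 CPM, and Prdx1 by 2.84 (SE 0.208, FDR = 4.86e-08). Gpr56 rose by 2.87 (FDR = 0.0286), Pclo by 0.92 (FDR = 0.00903) and Pvalb itself by 0.98 (SE 0.166, FDR = 0.00903), from 1118 ± 126.7 to 2208 CPM. Cabp2, a calcium-binding protein, stood at 69.0 CPM and had 0 reads in the Ai14 mice, so it was at least 21300-fold higher against a floor of 3 reads over the group (FDR = 0.0245). The proteasome ATPase Psmc4 rose by 0.55 (FDR = 0.0261), and the respiratory chain subunits Cox8a by 0.76 (FDR = 0.0371) and Cox4i1 by 0.61 (FDR = 0.0431). Ppp3r1, the regulatory subunit of calcineurin, fell by 0.63 (FDR = 0.0149). Altogether 64 of 25256 genes passed, 58 higher and 6 lower. Psmc4, Cox8a and Cox4i1 lost their call with library size alone and with limma-trend, Pvalb with limma-trend, and Cabp2 and Gpr56 with DESeq2.

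In the same Ai162 mouse, 29 of 37 oxidative phosphorylation genes rose adjusted over the list alone (2 over all genes; camera FDR = 1.8e-20). So did 13 of 25 proteasome genes (1 over all genes; camera FDR = 2.38e-09) and 10 of 42 ribosomal protein genes (0 over all genes; camera FDR = 1.72e-16, adjusted p = 0.245 with an estimated correlation). GABA synthesis and receptor genes had a median of -0.41, also with 1 gene at its bound (0 of 20 passed over all genes, 1 lower adjusted over the list alone; camera FDR = 2.36e-07). Markers of another cell type moved with them: 12 microglial genes had a median of 1.85, the same with 3 genes at their floor bound (0 passed over all genes, 2 higher adjusted over the list alone; camera FDR = 8.65e-07). Unfolded protein genes, with a median of -0.27 and 0 of 24 passing, were called downward (camera FDR = 0.00148, adjusted p = 0.254 with an estimated correlation).

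In the Ai163 mouse, Gstm5 rose by 1.56 (SE 0.137, FDR = 1.37e-06), to 633.9 CPM, and Pclo by 1.10 (FDR = 0.000507). AA465934, an uncharacterised transcript, stood at 128.3 CPM against 0.921 ± 0.525 CPM (7.13, SE 0.758, FDR = 2.93e-05), and Fn3krp, a fructosamine kinase relative, rose by 3.58 (FDR = 0.00377). The respiratory chain subunits Cox7a2 (0.89, FDR = 0.016) and Atp5o (0.58, FDR = 0.0259) rose. The vesicle fusion protein Vamp2 fell from 1220 ± 126.1 to 701.5 CPM (-0.80, FDR = 0.0127) and Pptc7 by 1.34 (FDR = 0.00455). In total 199 genes passed, 172 higher and 27 lower; AA465934 lost its call with DESeq2 and Atp5o with limma-trend. Of 37 oxidative phosphorylation genes 25 rose adjusted over the list alone (2 over all genes; camera FDR = 3.09e-11, adjusted p = 0.204 with an estimated correlation). Microglial genes had a median of 2.12, also with 4 genes at their bound (1 of 12 rose, 5 adjusted over the list alone; camera FDR = 9.34e-05, adjusted p = 0.0728 with an estimated correlation) and astrocyte genes 1.25, also with 1 at its bound (0 of 12 rose, 1 adjusted over the list alone; camera FDR = 0.0106, adjusted p = 0.105 with an estimated correlation). Of the 10 lists called, 0 held with an estimated correlation. Between the 2 lone mice, Ai163 against Ai162, edgeR called 0 genes (603 at an unadjusted p under 0.05), DESeq2 53 and limma-trend 150.

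The 3 Pvalb VISp mice with Ai139 differ from the Ai14 mice in driver, with its tamoxifen induction, and in reporter, so these effects cannot be separated. Pclo rose by 0.82 (SE 0.0984, FDR = 0.000171), the RNA-binding protein Rbm45 by 2.57 (SE 0.309, FDR = 0.000171), Gpr56 by 2.21 (FDR = 0.00801), the sphingomyelinase Smpd3 by 1.46 (FDR = 0.0169) and Slc35f4 by 1.41 (FDR = 0.043). Pvalb fell by 0.70 (SE 0.119, FDR = 0.0048), from 1118 ± 126.7 to 688.9 ± 149.6 CPM. Ift27, a transport protein of cilia, fell by 1.47 (SE 0.233, FDR = 0.00269), from 124.9 ± 26.1 to 45.1 ± 16.7 CPM. On the minus strand of chromosome 15 of GRCm38, Ift27 spans bases 78159463 to 78174107 and Pvalb bases 78191114 to 78206400. The small GTPase Arf5 fell by 0.89 (SE 0.0825, FDR = 4.38e-06), the clock gene Ciart by 1.93 (FDR = 0.00639), the sodium channel subunit Scn1b by 0.58 (FDR = 0.00455), the GABA receptor subunit Gabrd by 0.55 (FDR = 0.0354), Kcnh7 by 0.94 (FDR = 0.0117) and the cochaperone Stip1 by 0.41 (FDR = 0.043). In all, 182 genes passed, 122 higher and 60 lower. Oxidative phosphorylation genes, with 0 of 37 passing and a median of -0.09, were called downward (camera FDR = 0.036, adjusted p = 0.958 with an estimated correlation). Leaving out the second Ai139-hyg mouse left 105 genes and ended the calls of Pvalb, Gpr56, Ciart, Gabrd, Kcnh7, Slc35f4, Smpd3 and Stip1; leaving out the first ended those of Kcnh7, Slc35f4 and Stip1. Without both, 10 of the 13 genes picked lost their call, Ift27, Rbm45 and Pvalb among them, and with at least 15 cells per mouse 9 did.

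In ALM, 3 Pvalb mice with Ai139 against 5 with Ai14 gave 2 genes of 15626, both among those of the pooled comparison. Gstm5 rose by 1.33 (SE 0.102, FDR = 0.00298), from 204.1 ± 17.7 to 514.5 ± 33.6 CPM, and Pea15a by 1.24 (SE 0.0978, FDR = 0.00298), from 576.9 ± 57.0 to 1363 ± 84.0 CPM, each higher in 3 of 3 mice; with at least 15 cells per mouse both calls ended. Oxidative phosphorylation genes had a median of 0.14 (0 of 37 passed; camera FDR = 8.51e-06), proteasome genes 0.15 (0 of 25; camera FDR = 8.4e-05) and glutamate receptor genes -0.36 (0 of 24, 1 lower adjusted over the list alone; camera FDR = 3.67e-05); each had adjusted p = 0.391 with an estimated correlation. Whether the Ai139 effect differs between ALM and VISp was not tested.

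Sst interneurons with Ai148 beside Ai14 (2 mice) were compared with those with Ai14 alone (3 mice). Cabp2 stood at 415.5 ± 0.41 CPM with Ai148 and had 0 reads in the Ai14 mice, at least 85400-fold higher (FDR = 0.00194). Gstm5 rose by 2.01 (SE 0.0687, FDR = 0.00206), from 333.3 ± 0.501 to 1342 ± 124.7 CPM, the stress peptide Crh by 2.11 (SE 0.114, FDR = 0.0143), to 425.1 ± 63.1 CPM, and Slc35f4 by 2.00 (FDR = 0.0297). Calb2, a calcium buffer of some Sst cells, fell by 6.24 (SE 0.184, FDR = 0.00194), from 152.5 ± 16.7 to 2.02 ± 0.258 CPM, and Enpp2, a secreted phospholipase, by 3.06 (FDR = 0.043). Both Ai148 mice stood on the called side for each gene. Altogether 16 of 22390 genes passed, 13 higher and 3 lower; with 1 mouse left out in turn the count ran from 7 to 15. Enpp2 and Slc35f4 were lost without any 1 of the 5 mice, Crh without any 1 of the 3 Ai14 mice and Cabp2 without the second Ai148 mouse. Within the named Sst clusters the calls of Calb2 and Enpp2 ended, and with limma-trend those of Calb2, Crh and Enpp2.

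Adjusted over the list alone, 7 of 37 oxidative phosphorylation genes rose in Sst cells with Ai148 (camera FDR = 6.06e-09, adjusted p = 0.326 with an estimated correlation), as did 11 of 25 proteasome genes (camera FDR = 4.7e-08, adjusted p = 0.195 with an estimated correlation). GABAergic markers fell for 8 of 13 (camera FDR = 6.36e-05, adjusted p = 0.202 with an estimated correlation). Sst markers fell for 10 and rose for 3 of 19, 1 and 1 over all genes (camera FDR = 0.00251, adjusted p = 0.264 with an estimated correlation). Oligodendrocyte markers fell for 10 of 15 with a median of -4.82, or -4.02 with 2 genes at their bound (camera FDR = 4.7e-08, adjusted p = 0.195 with an estimated correlation). Astrocyte markers rose for 6 of 12 with a median of 3.00 (camera FDR = 1.68e-05, adjusted p = 0.37 with an estimated correlation). Of the 13 lists called, 0 held with an estimated correlation. The Ai148 cells were sorted on green and red fluorescence and the Ai14 cells on red alone.

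The Rbp4 mouse with Ai148, against 13 mice with Ai14, differed in genes that mark layer 5 types. Of its 87 cells 1 lay in the clusters named for layer 5, which held most cells of the Ai14 mice, so different clusters were compared. Tac2, which encodes neurokinin B, stood at 2233 CPM against 0.437 ± 0.467 CPM (12.10, SE 0.764, FDR = 2.9e-07), and Cabp2 at 73.1 CPM against 0 reads, at least 34800-fold higher (FDR = 0.00647). Rab3b, a vesicle GTPase, rose by 2.11 (SE 0.311, FDR = 0.00239), Crym, a marker of pyramidal-tract neurons, by 1.51 (FDR = 0.0187), Ubb by 0.61 (FDR = 0.0146), Psmc1 by 0.48 (FDR = 0.0432) and Ifi27, an interferon-inducible gene, by 1.49 (FDR = 0.00167). Lower genes included the layer 5 markers Hsd11b1 (-5.52, FDR = 0.0236), Npr3 (-4.46, FDR = 0.0292) and Etv1 (-1.66, FDR = 0.0321), the chemokine Cxcl12 (-5.99, FDR = 0.00239), the vesicle protein Synpr (-7.33, FDR = 0.000559) and Adcyap1, the peptide PACAP (-3.71, FDR = 0.0166). The signalling regulator Rgs4 fell from 1136 ± 246.9 to 269.0 CPM (-2.08, FDR = 0.0101) and Gria3 by 0.95 (FDR = 0.0135). In total 336 of 27429 genes passed, 165 higher and 171 lower. With limma-trend Crym, Psmc1, Npr3, Cxcl12 and Synpr lost their call. Against the 1 control mouse of the same period 15 of the 20 genes picked did, but with 1 mouse on each side this cannot separate period from reporter.

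Among the lists in the Rbp4 comparison, 2 of 25 proteasome genes rose (3 adjusted over the list alone; camera FDR = 2.64e-05, adjusted p = 0.263 with an estimated correlation). Potassium and sodium channel genes fell for 2 of 29 (7 adjusted over the list alone; camera FDR = 0.000359, adjusted p = 0.227 with an estimated correlation) and calcium buffering genes for 2 of 28 (7 lower and 1 higher adjusted over the list alone; camera FDR = 0.0166, adjusted p = 0.227 with an estimated correlation). Pyramidal-tract markers fell for 2 and rose for 1 of 12, with a median of -2.77, or -1.55 with 3 genes at their bound (camera FDR = 0.00443, adjusted p = 0.264 with an estimated correlation). Of the 15 lists called, 0 held with an estimated correlation.

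Layer 4 neurons of the Scnn1a driver with Ai139 (3 mice) against 1 mouse with Ai14 gave 0 genes by edgeR of 16638 tested, with 1365 at an unadjusted p under 0.05; DESeq2 called 1601 and limma-trend 0. Adjusted over the list alone, 32 of 37 oxidative phosphorylation genes rose with a median of 0.72 (camera FDR = 4.54e-26, adjusted p = 0.215 with an estimated correlation), and 6 of 25 proteasome genes rose (camera FDR = 1.99e-13, adjusted p = 0.215 with an estimated correlation). Potassium and sodium channel genes fell for 7 of 29 (camera FDR = 7.41e-06, adjusted p = 0.329 with an estimated correlation). Of the 9 lists called, 0 held with an estimated correlation. The Ai139 libraries were all prepared in the later period and the Ai14 library in the earlier one, so period and reporter cannot be told apart in this comparison. RNA quality differed too: the Ai139 cells had a median intron share of 15.7% and a mean of 6201 genes detected at matched depth, against 36.6% and 7659 in the Ai14 mouse.

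The Snap25 mice without a transgenic reporter, whose cells carried EGFP, were compared with Snap25 mice with Ai14, first in glutamatergic cells (2 mice against 11). Interferon-stimulated genes were high in both mice. Ifi44 stood at 136.7 ± 37.2 CPM against 0.00305 CPM (15.72, SE 0.388, FDR = 2.53e-11), Isg15, a ubiquitin-like modifier, at 436.4 ± 42.1 against 0.633 CPM (9.43, SE 0.336, FDR = 1.24e-09), and Stat1, the transcription factor of interferon signalling, at 291.1 ± 124.9 against 11.9 ± 1.49 CPM (4.61, SE 0.149, FDR = 4.8e-10). Oasl2 at 336.1 ± 135.6 CPM, Rsad2 at 49.8 ± 23.4 CPM and the GTPase Iigp1 at 270.5 ± 338.5 CPM had 0 reads in the Ai14 mice. They were at least 174000-fold (FDR = 0.000631), at least 25400-fold (FDR = 0.00182) and at least 116000-fold higher (FDR = 0.0158). The mice differed in some of these genes: Iigp1 stood at 31.2 CPM in 1 mouse and 509.9 CPM in the other. Of 28 interferon-stimulated genes, 27 rose and 0 fell, 28 adjusted over the list alone, with a median of 8.18, the same with 5 genes at their bound (camera FDR = 1.24e-78).

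**Figure D2:**
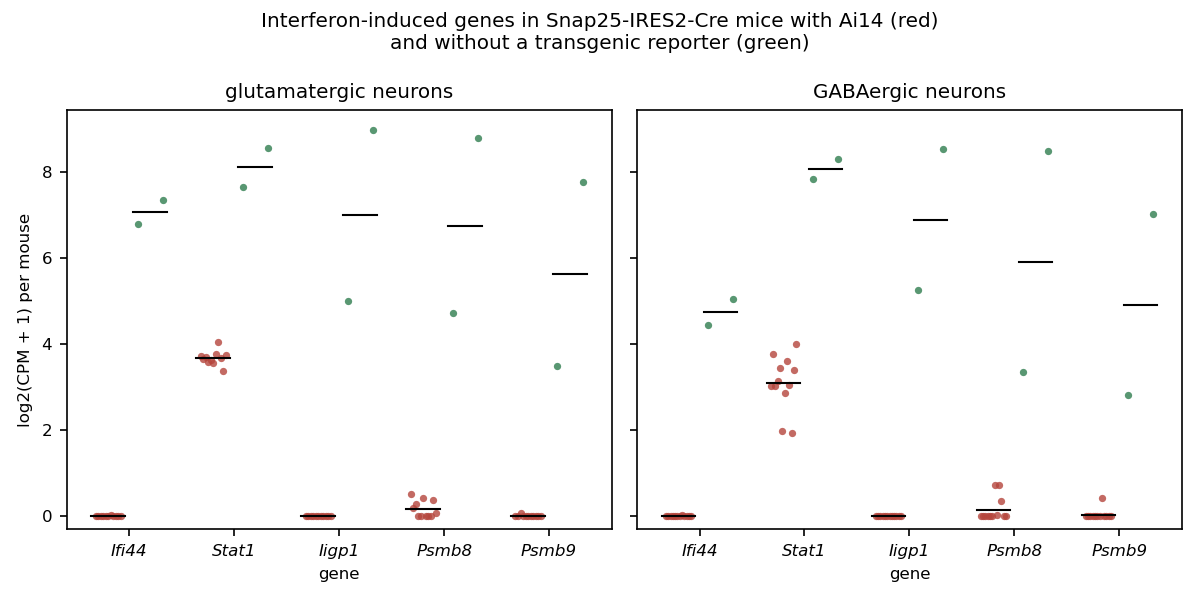
Level of Ifi44, Stat1, Iigp1, Psmb8 and Psmb9 as log2(CPM + 1), 1 point per mouse and class, in Snap25 mice with Ai14 (red) and without a transgenic reporter (green); lines are group means. In glutamatergic cells, Stat1 lay between 202.7 and 379.4 CPM in the 2 mice without a transgenic reporter and at most at 15.5 CPM in Ai14 mice.

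Antigen presentation rose with the interferon genes. Of 16 MHC class I genes, 13 rose and 1 fell, 13 and 2 adjusted over the list alone, with a median of 2.99 (camera FDR = 6.32e-18, adjusted p = 0.053 with an estimated correlation). The immunoproteasome subunits Psmb8 (10.42, SE 0.824, FDR = 5.02e-06) and Psmb9 (13.06, SE 0.913, FDR = 1.45e-06) and the class I heavy chain H2-D1 (SE 0.305, FDR = 3.38e-06, 734.2 ± 708.5 against 44.2 CPM) were among them. Of 10 microglial genes, 1 rose (2 adjusted over the list alone; median 2.32, camera FDR = 0.00633, adjusted p = 0.273 with an estimated correlation). Of 25 proteasome and ubiquitin genes, 13 rose and 0 fell, 20 and 1 adjusted over the list alone (camera FDR = 2.45e-13, adjusted p = 0.0901 with an estimated correlation). Other genes that rose were Ddit3, a factor of the integrated stress response, by 1.62 (FDR = 3.45e-05), the immediate early gene Jun by 1.59 (FDR = 0.00155), the cell death gene Bax by 0.52 (FDR = 0.0111) and the secreted peptide Vgf by 0.69 (FDR = 0.0122). Moxd1 at 3.51 CPM (9.18, FDR = 5.39e-05) and Nxph4 at 2.71 CPM (7.52, FDR = 0.00745) were 2 of the 4 of 13 layer 6 markers that rose; that list was not called (camera FDR = 0.16).

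Ribosomal protein genes rose for 26 of 42 in these glutamatergic cells, 39 adjusted over the list alone (camera FDR = 3.18e-29). Oxidative phosphorylation genes rose for 18 of 37, 29 adjusted over the list alone (camera FDR = 7.6e-20). Cholesterol synthesis genes fell for 3 of 20, 8 adjusted over the list alone: Hmgcs1 by 1.43 (FDR = 0.0075), Dhcr24 by 1.09 (FDR = 0.00422) and the sterol regulator Srebf2 by 0.78 (FDR = 0.0467). Their camera FDR was 1.28e-08, and adjusted p = 0.14 with an estimated correlation. GABA synthesis and receptor genes fell for 4 of 19, among them Gabra1 (-0.70, FDR = 0.00746), Gabra4 (-0.78, FDR = 0.0205) and Gabbr2 (-0.85, FDR = 0.00757), 6 adjusted over the list alone (camera FDR = 7.23e-07). Vesicle genes fell for 2 of 29, 8 adjusted over the list alone, with Nrxn1 at -0.51 (FDR = 0.0391) and Sv2b at -0.47 (FDR = 0.0287) (camera FDR = 0.0018). The calcium channel subunit Cacnb4 fell by 0.90 (FDR = 0.00348), the calcium-binding protein Necab1 by 1.03 (SE 0.111, FDR = 0.000112) and the guidance cue Sema3a by 1.41 (FDR = 0.00455).

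Over all 24091 genes tested in the glutamatergic cells, 969 passed, 715 higher and 254 lower; with library size as the only scaling it was 837, with 500 higher and 337 lower. Of the 15 lists called, 5 held with an estimated correlation. The cells without a transgenic reporter had 7327 ± 139.9 genes detected at matched depth against 8259 ± 349.2 (difference -932.2, exact permutation p = 0.0128, the smallest possible for 2 mice against 11), and an intron share of 12.4% ± 0.428 against 19.0% ± 3.51 (difference -6.57 percentage points, exact permutation p = 0.0385). Both mice were prepared in the later period and all 11 Ai14 mice earlier, so period and group cannot be told apart by this comparison alone. Without the first of the 2 mice 533 genes passed and without the second 123. The calls of Hmgcs1, Srebf2, Bax, Vgf, Gabra4, Nrxn1 and Sv2b ended in both cases, those of Dhcr24 and Nxph4 without the first, and those of Cacnb4, Gabbr2, Gabra1 and Sema3a without the second. With layer 5 dissections only, 17 of 32 picked genes lost their call, among them Ddit3, Jun and Necab1. With DESeq2 Psmb9, Moxd1 and Nxph4 lost it, and with limma-trend 9 of 34 did, Ddit3, Jun, Bax and Vgf among them.

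GABAergic cells of the same mice (2 against 12) showed the interferon genes again. Ifi44 stood at 26.4 ± 8.11 CPM against 0.00109 CPM (12.85, SE 0.616, FDR = 3.52e-08), Stat1 at 271.8 ± 61.6 against 8.36 ± 3.61 CPM (5.02, SE 0.362, FDR = 3.21e-06) and Bst2, a restriction factor of enveloped viruses, at 134.9 ± 8.62 CPM (12.44, FDR = 6.38e-06). Gbp3 and Iigp1, with 0 reads in the Ai14 mice, were at least 14100-fold (FDR = 0.00593) and at least 61300-fold higher (FDR = 0.0309), and the antiviral gene Samd9l rose (13.33, FDR = 4.61e-08). Of 25 interferon-stimulated genes, 18 rose and 0 fell, 24 adjusted over the list alone, with a median of 7.44, or 7.41 with 4 genes at their bound (camera FDR = 5.13e-71). Of 16 MHC class I genes, 10 rose and 1 fell, 14 and 2 adjusted over the list alone (median 3.36, camera FDR = 1.61e-21): B2m, the class I light chain, stood at 2311 ± 2231 against 110.3 CPM (4.39, SE 0.313, FDR = 3.21e-06), and Tapbp (2.89, FDR = 8.62e-06), Psmb8 (10.44, FDR = 0.000467), Psmb9 (10.87, FDR = 0.000432) and Psmb10 (1.68, FDR = 1.49e-05) rose.

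Other groups moved in the GABAergic cells as well. Of 42 ribosomal protein genes 8 rose, 26 adjusted over the list alone (camera FDR = 8.53e-18, adjusted p = 0.0929 with an estimated correlation). Of 37 oxidative phosphorylation genes 6 rose, 25 adjusted over the list alone (camera FDR = 3.78e-17, adjusted p = 0.0678 with an estimated correlation). GABA synthesis and receptor genes fell for 1 of 20, Gabra1 (-0.81, FDR = 0.00745), 5 adjusted over the list alone (camera FDR = 7.95e-08). The cannabinoid receptor Cnr1 (-1.32, FDR = 0.0095) was the 1 of 18 Vip, Lamp5 and Sncg markers that fell, 4 adjusted over the list alone (camera FDR = 0.00014, adjusted p = 0.0796 with an estimated correlation). Gria2 fell by 0.68 (FDR = 0.0311), the 1 of 26 glutamate receptor genes to do so, 4 adjusted over the list alone (camera FDR = 6.87e-05). The scaffold Magi1 fell by 1.40 (FDR = 0.00152), the adhesion molecule Ncam2 by 1.47 (FDR = 0.0126), Fgd4 by 1.85 (FDR = 0.00687) and the cochaperone Chordc1 by 0.85 (FDR = 0.00357). Of the 13 lists called, 4 held with an estimated correlation.

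In the GABAergic cells 267 of 22193 genes passed, 171 higher and 96 lower. Genes detected stood at 6705 ± 36.8 against 7252 ± 444.9 (difference -546.7) and the intron share at 12.4% ± 0.686 against 16.2% ± 3.40 (difference -3.84 percentage points), each with an exact permutation p of 0.121. Without the first mouse 245 genes passed, and the calls of Cnr1, Fgd4, Gria2 and Ncam2 ended. Without the second 131 passed, and those of Chordc1, Cnr1, Gabra1, Gbp3, Gria2, Iigp1, Ncam2, Psmb8 and Psmb9 ended. With layer 5 dissections only, 22 of the 28 genes picked lost their call, including all named above except Stat1, Bst2, Samd9l, B2m, Psmb8 and Psmb10. With DESeq2 Bst2 and Psmb9 lost it, and with limma-trend 7 of the 28. The GABAergic share of sorted cells was 21.9% ± 13.4 in the 2 mice and 42.2% ± 21.2 in 12 Ai14 mice (difference -20.3 percentage points, exact permutation p = 0.231); the 2 groups were sorted on different fluorescence and dissected layers were not matched.

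Whether the reporter effect differs between the classes was tested on the difference within each mouse with limma (2 mice against 11), and 12 of 23206 genes passed, 3 higher and 9 lower in GABAergic relative to glutamatergic cells. Ifi44 (FDR = 0.000265) and Rsad2 (FDR = 0.0059) rose less in GABAergic cells; as both lie at or near 0 reads in Ai14 mice, the prior count sets the size of these differences. The peptide receptor Grpr had changes of -1.71 and 4.08 (difference -5.79, FDR = 0.00542), and the peptide Vip -1.12 and -5.44 (difference 4.32, SE 0.531, FDR = 0.00717); with cells weighted alike in limma-trend the Vip difference was -2.89 and did not pass, and without the second mouse its call ended. Grpr lost its call with limma-trend and Ifi44 with exon plus intron counts. The interferon list lay lower in GABAergic cells, with 2 of 25 genes passing and 6 lower and 3 higher adjusted over the list alone (median -0.85, camera FDR = 0.0116, adjusted p = 0.508 with an estimated correlation). Without the first mouse 81 genes passed and without the second 69.

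The Pvalb and Sst drivers were compared with each other in VISp mice with Ai14 (16 against 3) to see which interneurons each marks. The driver genes separated the groups: Pvalb stood at 1122 ± 127.0 against 75.7 ± 25.4 CPM (3.89, SE 0.191, FDR = 4.8e-11) and Sst at 64.5 ± 141.1 against 6457 ± 1002 CPM (-6.64, SE 1.24, FDR = 0.000703). Pvalb cells were higher in Pdlim3, an actin-associated protein (9.84, FDR = 8.81e-09), Syt2, the fast synaptic calcium sensor (7.24, FDR = 3.06e-08), the respiratory chain subunit Cox6a2 (4.13, FDR = 6.22e-10, 394.3 ± 71.7 against 22.6 CPM), the cation channel Trpc3 (4.68, FDR = 6.17e-08), the neuregulin receptor Erbb4 (1.95, FDR = 3.52e-09) and the peptide Cck (3.27, FDR = 7.98e-08). Sst cells were higher in Calb2 (-12.78, SE 0.451, FDR = 3.46e-13), the opioid peptide precursor Pdyn (-12.61, FDR = 1.04e-10, 534.4 CPM), Nts (-11.19, FDR = 1.48e-09), the myosin Myh8 (-9.28, FDR = 2.69e-06) and Calb1 (-2.17, FDR = 3.31e-05). Chodl, at 41.6 ± 14.0 CPM in Sst cells, had 0 reads in Pvalb cells, at least 13600-fold lower (FDR = 2.58e-05).

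Sst markers were lower in Pvalb cells for 15 of 19 genes with none higher, 17 and 1 adjusted over the list alone (median -5.07, also with 2 genes at their bound, camera FDR = 2.13e-24). Pvalb markers were higher for 10 of 18 and lower for 3, 12 and 3 adjusted over the list alone (median 1.07, also with 1 gene at its bound, camera FDR = 2.37e-08). Oxidative phosphorylation genes were higher in Pvalb cells for 30 of 37, 35 adjusted over the list alone (median 0.46, camera FDR = 1.28e-24); Atp5b stood at 4653 ± 352.4 against 2926 ± 80.7 CPM (0.67, FDR = 4.36e-07). Of 29 potassium and sodium channel genes 14 were higher and 6 lower, 16 and 10 adjusted over the list alone (camera FDR = 0.000966): Kcnc1, a channel of fast spiking (1.74, FDR = 2.28e-08), Kcnh7 (2.39, FDR = 2.54e-08) and Scn1b (1.26, FDR = 2.24e-08) were higher. Of 20 GABA synthesis and receptor genes 9 were higher and 4 lower, 10 and 5 adjusted over the list alone (camera FDR = 0.00126, adjusted p = 0.068 with an estimated correlation), with the receptor subunits Gabrd (2.72, FDR = 4.8e-11) and Gabra1 (1.69, FDR = 2.81e-08) and the GABA transporter Slc6a1 (1.22, FDR = 1.16e-07) higher. Of 20 neuropeptide genes 9 were lower and 4 higher, 10 and 5 adjusted over the list alone (camera FDR = 0.00051).

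Cholesterol synthesis was lower in Pvalb cells for 7 of 20 genes, 8 adjusted over the list alone (camera FDR = 0.000124), among them Fdft1 (-1.65, FDR = 3.68e-07), Fdps (-1.31, FDR = 7.04e-07) and Srebf2 (-1.32, FDR = 3.84e-05). Interferon-stimulated genes were lower for 5 of 16, 5 adjusted over the list alone (camera FDR = 0.00164). The complexins that clamp vesicle fusion went opposite ways: Cplx1 was higher by 1.49 (FDR = 1.15e-08) and Cplx2 was at -3.78 (FDR = 1.46e-07). Oligodendrocyte markers were lower for 3 of 13 (median -2.33, camera FDR = 1.19e-06, adjusted p = 0.22 with an estimated correlation). Of the 13 lists called, 8 held with an estimated correlation. Of 21411 genes 2953 passed, 1483 higher and 1470 lower in Pvalb cells, and between 1974 and 2157 with 1 Sst mouse left out. With DESeq2 Pdlim3 and Pdyn lost their call.

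The Rbp4 driver was set against the driver of all neurons, Snap25, in glutamatergic cells from layer 5 dissections with Ai14 (8 mice against 9). Snap25 itself, the membrane fusion protein whose gene carries the Snap25-IRES2-Cre insertion, stood at 9182 ± 964.2 CPM in Rbp4 mice and 4321 ± 344.5 CPM in Snap25 mice (1.09, SE 0.0641, FDR = 2.19e-08), with 8 of 8 Rbp4 mice above the Snap25 mean. The layer 5 marker Hsd11b1 was higher in Rbp4 mice by 2.23 (SE 0.379, FDR = 0.0212), at 87.8 ± 26.1 against 18.6 ± 16.6 CPM. The actin-binding peptide gene Tmsb10 rose by 0.77 (SE 0.0955, FDR = 0.00173) and the endocannabinoid-degrading lipase Mgll by 0.53 (FDR = 0.046). Lower in Rbp4 mice were Noc2l (-0.49, SE 0.0705, FDR = 0.00857), the ubiquitin-activating enzyme Uba1 (-0.39, FDR = 0.0259), the actin-disassembly factor Wdr1 (-0.67, FDR = 0.046) and the calcium-binding protein Calu (-0.47, FDR = 0.0491). Rbp4 itself had a fold change of 0.68 that did not pass (FDR = 0.154). Altogether 57 of 18893 genes passed, 41 higher and 16 lower; with DESeq2 size factors it was 29, 17 higher and 12 lower, with the DESeq2 Wald test 422, with limma-trend 21 and with at least 15 cells per mouse 1278. Within the named layer 5 clusters 14 of the 16 genes picked by the naming rule lost their call, including each one called by name for this comparison except Snap25.

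**Figure D3:**
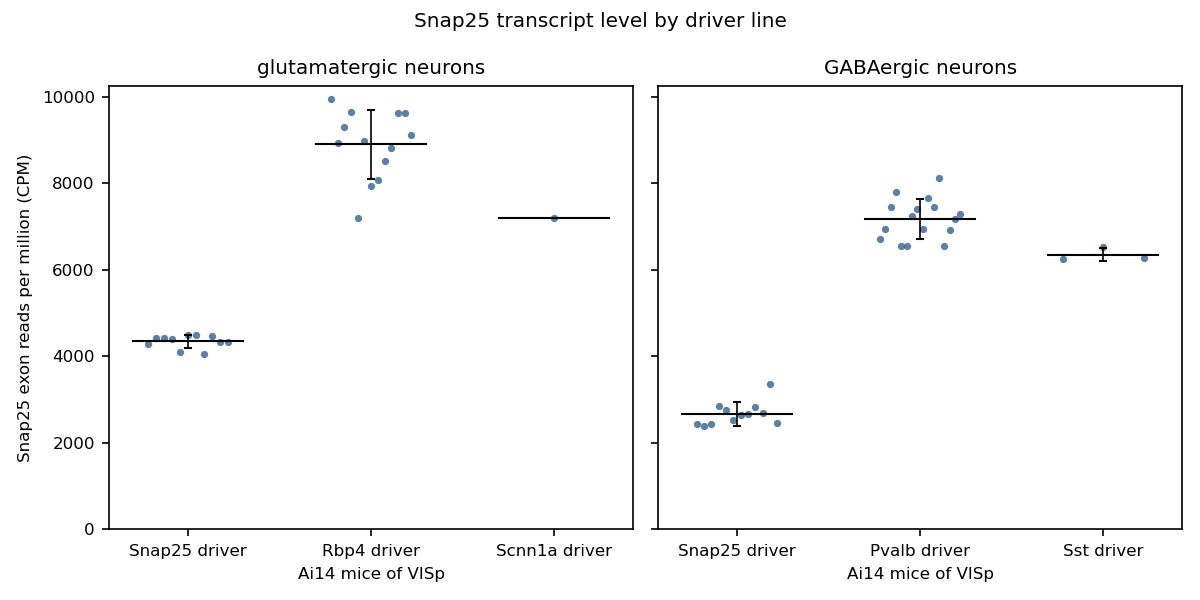
Level of Snap25 in CPM, 1 point per mouse, in glutamatergic and GABAergic cells of VISp mice with Ai14, by driver; black lines are means and error bars SD. Glutamatergic cells of 11 Snap25 mice lay between 4048 and 4484 CPM, and those of 14 mice with other drivers between 7188 and 9953 CPM.

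Oxidative phosphorylation genes were higher in Rbp4 mice for 4 of 37, with 16 higher and 1 lower adjusted over the list alone (camera FDR = 6.68e-08, adjusted p = 0.286 with an estimated correlation), among them Atp5j (0.28, FDR = 0.0212), Cox5a (0.27, FDR = 0.0355) and Cox4i1 (0.26, FDR = 0.0491). Ribosomal protein genes had 0 of 42 over all genes and 18 higher adjusted over the list alone (camera FDR = 1.35e-08, adjusted p = 0.286 with an estimated correlation). Near-projecting markers had a median of -2.65, with 0 of 7 passing and 4 lower adjusted over the list alone (camera FDR = 0.00255, adjusted p = 0.375 with an estimated correlation), and layer 6 markers -1.41, with 0 of 10 and 1 (camera FDR = 0.00239, adjusted p = 0.259 with an estimated correlation). Of the 9 lists called, 0 held with an estimated correlation.

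Cortical layers were compared within the Snap25 mice with Ai14, where L2/3, L4, L5 and L6 had been dissected apart (11 mice, with the mouse as a block; each layer against the mean of the others). Layer 2/3 cells were marked by Otof (8.67, SE 0.833, FDR = 1.2e-08), the lipase Lpl (7.21, FDR = 1.64e-08), Crh (6.75, FDR = 2.61e-06), the endoplasmic reticulum protein Wfs1 (4.01, FDR = 1.22e-09), the transcription factor Cux2 (3.94, FDR = 1.14e-07) and Calb1, a calcium buffer, at 1268 ± 210.1 against 86.7 ± 78.8 CPM (4.24, SE 0.228, FDR = 8.11e-14, 10 of 10 mice). The opioid peptide Penk (3.65, FDR = 0.000374) was also higher, while the layer 5 genes Fezf2 (-11.29, FDR = 5.6e-10), Crym (-8.35, FDR = 9.12e-08) and Rab3b (-3.37, FDR = 2.25e-09) were lower. Superficial markers were higher for 11 of 11 genes (median 3.61, camera FDR = 3.64e-29). Immediate early genes were higher for 9 of 25, with 14 higher and 1 lower adjusted over the list alone (camera FDR = 3.62e-06): the trophic factor Bdnf at 1.69 (FDR = 1.65e-05), Nr4a2 at 1.94 (FDR = 1.75e-05) and Plk2 at 0.98 (FDR = 1.04e-08). Cholesterol synthesis was lower for 8 of 20, 9 adjusted over the list alone (camera FDR = 3.72e-07).

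Other lists in layer 2/3 included glutamate receptors, higher for 10 of 26 and lower for 1 (14 and 1 adjusted over the list alone; camera FDR = 0.00066). Markers named for Sst interneurons were higher for 5 of 14 (7 adjusted over the list alone; camera FDR = 3.09e-05) and Vip, Lamp5 and Sncg markers for 5 of 12 (6 adjusted over the list alone; camera FDR = 0.00179). Layer 6 markers were lower for 5 of 11 with a median of -2.11, or -3.77 with 2 genes at their bound (camera FDR = 0.000156). Of the 13 lists called, 9 held with an estimated correlation. In total 2527 of 22478 genes passed for layer 2/3, 1541 higher and 986 lower.

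Layer 4 cells were marked by Rspo1, an activator of Wnt signalling (7.28, SE 0.982, FDR = 2.85e-06, 149.4 ± 75.2 against 6.68 CPM), by Scnn1a, the gene of the layer 4 driver (7.18, SE 1.01, FDR = 5.68e-06), and by the nuclear receptor Rorb at 287.9 ± 64.9 against 23.8 ± 34.1 CPM (6.11, SE 0.46, FDR = 9.42e-11, 9 of 9 mice). The adhesion molecule Nrxn1 was higher by 1.32 (SE 0.0566, FDR = 2.99e-16) and the kinase Camk4 by 1.48 (FDR = 2.55e-10), while Igfbp4 was lower by a fold change of -5.71 (FDR = 8.52e-11) and Id2 of -2.32 (FDR = 2.35e-07). Layer 4 markers were higher for 8 of 9 (median 4.56, camera FDR = 3.27e-16). Energy and protein folding genes were lower: oxidative phosphorylation for 25 of 37, 28 adjusted over the list alone (camera FDR = 1.99e-15, adjusted p = 0.0693 with an estimated correlation), with Atp5b at -0.53 (FDR = 7.33e-08), and heat shock genes for 12 of 16, 14 adjusted over the list alone (camera FDR = 2.08e-10), with Hsp90ab1 at -0.41 (FDR = 1.02e-05). Hspa5, the chaperone of the endoplasmic reticulum, was at -0.75 (FDR = 3.37e-05). Proteasome genes were lower for 12 of 25, 19 adjusted over the list alone (camera FDR = 1.27e-07).

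Potassium and sodium channel genes were higher in layer 4 for 14 of 29 and lower for 4, 17 and 4 adjusted over the list alone (camera FDR = 5.86e-05), with Kcna2 at 1.10 (FDR = 4.91e-07) and Kcnb1 at 0.89 (FDR = 3.53e-08). Layer 6 markers were lower for 7 of 11, with a median of -3.20, or -3.46 with 3 genes at their bound (camera FDR = 1.73e-05). Glutamatergic neuron markers were higher for 6 of 13 and lower for 3, 7 and 3 adjusted over the list alone (camera FDR = 0.0125, adjusted p = 0.165 with an estimated correlation). The vesicle and calcium channel lists were called upward with medians of 0.08 and 0.31 but means of -0.03 and -0.18 (camera FDR = 0.0157 and 0.0272), with 11 higher and 5 lower vesicle genes adjusted over the list alone; each had adjusted p = 0.24 with an estimated correlation. Of the 12 lists called, 6 held. For layer 4, 3424 genes passed, 1609 higher and 1815 lower.

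**Figure D4:**
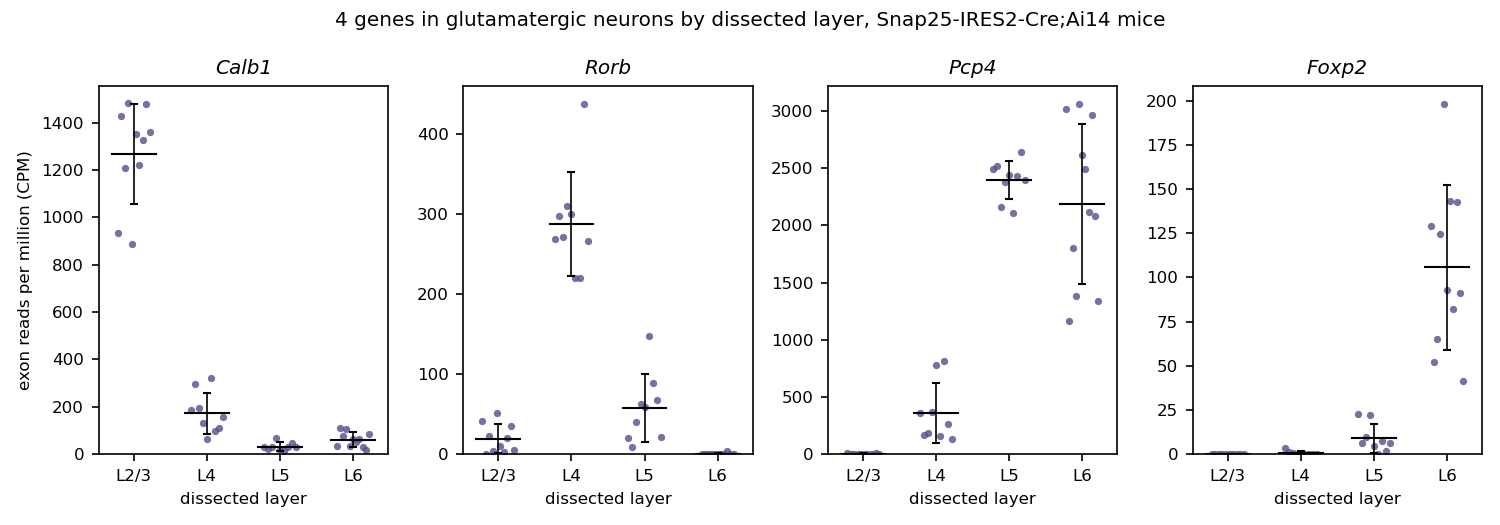
Level of Calb1, Rorb, Pcp4 and Foxp2 in CPM by dissected layer, 1 point per mouse and layer in Snap25 mice with Ai14; black lines are means and error bars SD. Calb1 averaged 1268 CPM in layer 2/3, Rorb 287.9 CPM in layer 4, Pcp4 2396 CPM in layer 5 and 2186 CPM in layer 6, and Foxp2 105.7 CPM in layer 6.

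Layer 5 cells were marked by the transcription factor Fezf2 (6.12, SE 0.535, FDR = 5.26e-09, 198.2 ± 64.0 against 38.5 CPM), Etv1 (4.26, SE 0.583, FDR = 1.33e-05, 196.5 CPM), Pcp4, a calmodulin regulator, at 2396 ± 168.0 against 910.4 CPM (4.73, SE 0.351, FDR = 1.54e-10) but close to its 2186 CPM in layer 6, and Il1rapl2 (5.72, FDR = 2.46e-06). Bcl11b (5.42, FDR = 1.66e-05) and Crym (5.00, FDR = 1.72e-06) were higher in 8 of 9 mice. Calb1 was lower (-2.86, FDR = 7.56e-07) and the complexin Cplx1 was higher by 1.55 (SE 0.103, FDR = 2.35e-11). Intratelencephalic markers were higher for 10 of 10 (median 4.36, camera FDR = 1.39e-18), pyramidal-tract markers for 8 of 11 (median 4.21, camera FDR = 3.39e-12) and near-projecting markers for 8 of 9, 9 adjusted over the list alone (camera FDR = 2.08e-08). Oxidative phosphorylation was higher for 22 of 37, 25 adjusted over the list alone (camera FDR = 1.29e-15, adjusted p = 0.0532 with an estimated correlation), with Atp5b at 0.47 (FDR = 1.38e-06). Cholesterol synthesis was higher for 5 of 20, 8 adjusted over the list alone (camera FDR = 2.65e-06, adjusted p = 0.0692 with an estimated correlation), with its rate-limiting enzyme Hmgcr at 0.79 (FDR = 0.00111).

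In layer 5, superficial markers were lower for 4 of 11, 6 adjusted over the list alone (camera FDR = 1.86e-07), and layer 6 markers higher for 5 of 11, 7 adjusted over the list alone (camera FDR = 9.54e-05). Markers named for Pvalb interneurons were higher for 5 of 17 and lower for 1, 10 and 2 adjusted over the list alone (camera FDR = 0.000886). Neuropeptides were higher for 4 of 20, with 8 higher and 1 lower adjusted over the list alone (camera FDR = 0.0103). Calcium buffering genes were lower for 7 of 28 and higher for 2, 9 and 4 adjusted over the list alone, with a median of -0.07 but a mean of 0.09 (downward, camera FDR = 0.000147). Of the 15 lists called, 8 held with an estimated correlation. For layer 5, 1455 genes passed, 1017 higher and 438 lower.

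Layer 6 cells were marked by the transcription factor Foxp2 at 105.7 ± 46.7 against 3.09 ± 6.06 CPM (7.98, SE 0.504, FDR = 1.56e-12, 11 of 11 mice), Sla (11.88, SE 0.69, FDR = 8.88e-13), the synaptotagmin Syt6 (11.05, FDR = 6.84e-11) and the small heat shock protein Cryab (3.88, FDR = 6.99e-08). The vesicular glutamate transporter Slc17a6 was at -12.41 (SE 0.659, FDR = 5.48e-14) and Rorb at -8.43 (FDR = 6.03e-10). Layer 6 markers were higher for 9 of 11, 11 adjusted over the list alone (median 4.72, also with 1 gene at its bound, camera FDR = 1.61e-26). Layer 4 markers were lower for 6 of 9, with 6 lower and 1 higher adjusted over the list alone (camera FDR = 1.28e-07), and superficial markers for 6 of 11, 7 adjusted over the list alone (camera FDR = 1.33e-05). Oxidative phosphorylation was higher for 17 of 37, with 25 higher and 1 lower adjusted over the list alone (camera FDR = 1.2e-09, adjusted p = 0.166 with an estimated correlation), and proteasome genes for 8 of 25, 14 adjusted over the list alone (camera FDR = 4.47e-06, adjusted p = 0.0798 with an estimated correlation). Of the 15 lists called, 3 held with an estimated correlation. For layer 6, 2346 genes passed, 1268 higher and 1078 lower, and over the 4 layers 5855 genes passed for at least 1.

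Pvalb neurons of ALM were compared with those of VISp in mice with Ai14 (5 against 16). ALM cells were higher in Ostn, a secreted peptide (2.38, SE 0.464, FDR = 0.0287, 142.0 ± 69.1 against 27.3 CPM), the growth factor Ptn (1.28, SE 0.212, FDR = 0.0118), Tac1, the substance P precursor (0.96, FDR = 0.0313, 2336 ± 575.1 against 1202 ± 336.4 CPM), Cck (0.88, FDR = 0.0388) and the kainate receptor Grik2 (0.67, FDR = 0.0118). Pdlim3 was lower, at 6.55 ± 4.45 against 71.3 ± 15.1 CPM (-3.41, SE 0.46, FDR = 0.00182, 5 of 5 mice), as were Cacna2d3 (-4.94, FDR = 0.0173), the teneurin Tenm2 (-1.23, SE 0.166, FDR = 0.00182), the peptide Pthlh (-1.46, FDR = 0.00681), Tnfrsf12a (-1.47, FDR = 0.0173), the NMDA receptor subunit Grin1 (-0.71, FDR = 0.0173) and the cell cycle inhibitor Cdkn1a (-2.34, FDR = 0.0197). Scg2 (-0.66, FDR = 0.0287), Crem (-1.46, FDR = 0.0339) and Vgf (-1.11, FDR = 0.0368) were also lower. Of 23 immediate early genes 0 passed over all genes and 6 were lower adjusted over the list alone (median -0.52, camera FDR = 2.86e-05, adjusted p = 0.318 with an estimated correlation). In all 53 of 18590 genes passed, 25 higher and 28 lower. Leaving out single ALM mice, the fourth to the eighth in turn, gave 27, 63, 21, 178 and 38 genes, and 9 of the 18 genes that the naming rule picked kept their call each time. With layer 5 dissections only 0 of the 18 kept it, and with at least 15 cells per mouse 2 did. With limma-trend Ptn, Cck, Grik2, Cacna2d3, Scg2, Crem and Vgf lost it.

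Named clusters describe the cells each driver marked in VISp mice with Ai14. Pvalb-like clusters held 95.7% ± 5.32 of cells of Pvalb mice (SD, n = 16) and Sst-like clusters 67.5% ± 6.28 of those of Sst mice (n = 3). In Rbp4 mice, layer 5 intratelencephalic-like clusters held 29.3% ± 7.65 and pyramidal-tract-like ones 35.7% ± 15.4 (n = 13). Of the unnamed clusters, 1 had 5 of 10 Sst markers and 1 was led by the layer 5 marker Hsd11b1. In the 1 Scnn1a mouse, layer 4-like clusters held 115 of 129 cells (95% exact binomial interval 82.5% to 93.9%). All were sorted on red fluorescence and dissected layers differed between drivers, so shares hold for these cells.

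Of the 32 lists fixed beforehand, endothelial and vascular markers and the p53 and cell death genes were called in no comparison. The lowest camera FDR of the endothelial list was 0.0638, for Pvalb against Sst cells (14 genes, median -1.53). That of the p53 list was 0.121, for glutamatergic Snap25 cells without a transgenic reporter (20 genes, median 0.24).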

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

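The tests of explanations and the splits of mice in this part were chosen only after the results were seen, except that the Snap25 value within named clusters had been planned.

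Gstm5, Prdx1 and Pea15a were higher with a TIGRE reporter. In early libraries (before December 2017) the lowest of the 3 fold changes was 0.888, arguing against period as the whole cause. In the green-sorted Snap25 mice the highest fold change plus 2 SE over the 3 genes and both classes was 0.588, below the 1.10 of Pea15a, which argues against the green gate. No counted gene shares a word of 25 bases with Gstm5, and summed with the 2 that share any with Pea15a the difference was 1.241, which argues against reads of gene copies. Prdx1 differed by 1.77 with the 3 genes that share at least 50 words. With any 1 shared word, the definition tried first, it was summed over 564 genes and differed by -0.0143, so for Prdx1 this rests on the stricter definition, set after that value was seen. A reporter effect may remain, as a hypothesis, and in Pvalb mice with Ai139, most of the early TIGRE mice, the driver differs.

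Interferon-stimulated genes were higher in the Snap25 mice without a transgenic reporter. In the 7 other mice prepared from December 2017, the highest median difference of the 27 called genes was 0.00571, against 3.45 to 5.37 in the mice without a transgenic reporter, which argues against preparation period. In the 5 of them that carry no Ai14 it was at most 0, which argues against the missing Ai14 allele. The highest of 5 microglial genes (Cx3cr1, C1qa, C1qb, Csf1r, P2ry12) in those mice stood at 3.567 CPM, while the called interferon genes had medians from 43.5 to 109.1 CPM, which argues against microglia among the green-sorted cells. The labels state a virus injection for no single mouse; a virus and its surgery may each contribute and were not tested apart.

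Snap25 was lower in mice with the Snap25-IRES2-Cre driver than in Rbp4 mice. Within the named layer 5 clusters the fold change was 0.944, which argues against different cell types. The third quartile of the other 28 vesicle genes was 0.154, which argues against a shift of vesicle transcripts as a whole. In GABAergic cells of Ai14 mice Snap25 stood at 2664 ± 272 CPM in 12 Snap25 mice and 7042 ± 532 CPM in 19 mice with other drivers. An effect of the driver insertion may remain, as a hypothesis, and was not tested.

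Other splits of the same mice gave fewer genes than the real grouping in each case. This bears on chance, not on driver or period. Counts: TIGRE 1341 against at most 150 in 60 splits, Pvalb Ai139 182 against 84 in 100 and ALM Ai139 2 against 1 in 56. Pvalb against Sst had 2953 against 4 in 100, Rbp4 against Snap25 57 against 0 in 100, ALM against VISp 53 against 4 in 100. For layers, with layer names exchanged within mice in 22 splits, it was 5855 over the 4 layers against 120, 2527 against 0 for layer 2/3, 3424 against 1 for layer 4, 1455 against 2 for layer 5 and 2346 against 119 for layer 6.

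Of 140 groups of 4 to 10 samples, 22 had 1 mouse far from the others, where chance gives about 1 in 20, or 7. Each is given as its gap over the whole range, then its CPM and the range of the other mice. In ALM Pvalb mice with Ai14, these were Tnfrsf12a 0.743 (43.4 against 23.7 to 28.8), Cib2 0.786 (11.3 against 30.0 to 35.1), Rfx7 0.763 (43.4 against 18.0 to 24.1), Setd5 0.745 (16.3 against 32.9 to 38.6), genes detected 0.837 (7126 against 8188 to 8395 genes) and intron share 0.797 (8.00% against 12.1% to 13.1%). In layer 2/3 they were Crh 0.563 (214.4 against 1.53 to 94.5), Nr4a2 0.5 (370.9 against 38.8 to 204.8), Otof 0.561 (94.7 against 18.4 to 51.9) and Penk 0.604 (686.5 against 20.7 to 284.6). In layer 4 they were Igfbp4 0.757 (15.5 against 0.471 to 4.14) and Rorb 0.586 (438.1 against 219.5 to 310.0). In layer 5, 1 mouse stood apart in Bcl11b 0.543 (3.90 against 33.2 to 57.8), Fezf2 0.52 (50.4 against 169.2 to 278.9) and Il1rapl2 0.549 (87.4 against 11.1 to 45.5). Among layer 5 Snap25 mice they were Calu 0.622 (above the others at 77.5 to 101.2), Cox4i1 0.845 (1305 against 1009 to 1055), Mgll 0.502 (86.7 against 48.5 to 67.5), Noc2l 0.632 (97.6, above the others from 73.1) and Tmsb10 0.647 (77.0 against 114.5 to 135.0), and among Rbp4 mice Snap25 0.577 (7032 against 8837 to 10160) and Uba1 0.593 (152.2 against 184.3 to 206.3).

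Between the Snap25 classes limma called 12 genes (its 1 self-test call was false), among them Grpr (-5.789), Ifi44 (-2.253), Rsad2 (-2.288) and Vip (4.318). The interferon, oligodendrocyte and proteasome lists were called too (camera FDR = 0.0116 each, with no call at an estimated correlation). The WPRE part of a viral tdTomato construct, listed in the deposited table and used in no comparison, stood at 3837 CPM in GABAergic cells of 1 mouse and 2759 CPM in glutamatergic cells of 2 mice without a transgenic reporter, against at most 29.9 CPM elsewhere. No WPRE part is listed for the EGFP virus that the protocol names.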

How the results depend on the processing

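The restriction to libraries prepared before December 2017 was chosen only after the results were seen; the other alternatives were planned.

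Of 178 alternative counts of genes, 127 stayed within 1.5 times the reported count, as did 37 of the 50 counts that left out 1 mouse. Of 3835 values of named genes under the alternatives, 3388 kept direction and call, 446 lost the call and 1 reversed: Vip, in the difference between classes, was -2.887 with limma-trend. No scaling moved the median of all genes by more than 0.1.

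With the DESeq2 Wald test, counts were 344 for Ai162, 648 for Pvalb Ai139, 53 for Ai163 against Ai162, 52 for ALM Ai139, 2515 for Sst Ai148, 1516 for Rbp4 Ai148, 1601 for Scnn1a, 1806 and 1025 for glutamatergic and GABAergic Snap25 cells, 422 for Rbp4 against Snap25, 2467 for layer 5 and 483 for ALM against VISp. With limma-trend they were 3770 for TIGRE (423 higher, 3347 lower), 98 for Ai162, 942 for Ai163, 150 for Ai163 against Ai162, 77 for Sst, 1185 for Rbp4 Ai148, 1874 and 529 for glutamatergic and GABAergic Snap25 cells, 28 for the difference between classes, 21 for Rbp4 against Snap25 and 81 for ALM against VISp. The cause was not tested.

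With exon plus intron counts, 2290 genes passed for TIGRE, 118 for Ai162, 964 for Ai163, 384 for Pvalb Ai139, 533 for GABAergic Snap25 cells, 21 for Rbp4 against Snap25 and 81 for ALM against VISp. Without the low-count filter, which tests more genes, it was 2359 for TIGRE, 459 for GABAergic Snap25 cells, 153 for the difference between classes and 189 for ALM against VISp. With at least 15 cells per mouse, which leaves fewer mice, it was 100 for Ai162, 98 for Pvalb Ai139, 0 for ALM Ai139, 1278 for Rbp4 against Snap25 and 11 for ALM against VISp. With DESeq2 size factors, Rbp4 against Snap25 had 29. The cause was not tested.

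Other choices of cells and mice changed counts as follows. TIGRE had 328 within named clusters, 385 with library period as a covariate, 113 before December 2017 and 2152 without the Pvalb-T2A-CreERT2 mice. Rbp4 Ai148 had 74 against the 1 control mouse prepared in 2018 (1 mouse against 1, with spread taken from the other mice) and 1485 with layer 5 dissections only, which also gave 223 and 31 for glutamatergic and GABAergic Snap25 cells and 2 for ALM against VISp. Rbp4 against Snap25 had 35 within named clusters, of which 2 were shared with the reported genes, and 23 with Rbp4 mice prepared in 2016. The cause was not tested.

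Leaving out 1 mouse in turn, counts ran from 105 (without the second Ai139-hyg mouse) to 250 for Pvalb Ai139, 7 to 15 for Sst (7 without the first Ai14 mouse), 123 to 533 for glutamatergic and 131 to 245 for GABAergic Snap25 cells (lowest without the second mouse), 69 to 81 for the difference between classes, and 21 to 178 for ALM against VISp (without the sixth and the seventh ALM mouse). Genes detected in glutamatergic cells differed by -1031 to -833.3 and the intron share by -6.875 to -6.27 percentage points, with exact p = 0.0833 and exact p = 0.167 in both cases; with 1 mouse left, 0.0833 is the smallest possible.

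With the estimated correlation, the number of lists called was 5 for TIGRE, 7 for Ai162, 5 and 4 for glutamatergic and GABAergic Snap25 cells, 8 for Pvalb against Sst, 6, 8 and 3 for layers 4, 5 and 6, and 0 for Ai163, Pvalb Ai139, ALM Ai139, Sst, Rbp4 Ai148, Scnn1a, the difference between classes, Rbp4 against Snap25 and ALM against VISp. Genes detected in GABAergic Snap25 cells differed by -1089 without thinning (exact p = 0.011). The difference in the share of cells with at least 1 GCaMP6 read was 1.845 percentage points (exact p = 0.212), and the Sst-like share was 85.81% at a clustering resolution of 0.5. The cause was not tested.

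Restricting Rbp4 Ai148 to named clusters was not possible, since its mouse had 1 such cell, and the DESeq2 Wald test was not run for the difference between classes, which is a difference within mice.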

Other observations

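The test in this part was chosen only after the result was seen.

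ALM mice with Ai14 of the other drivers, in no comparison, gave 41 cells from 5 Snap25 mice and 11 cells from 3 Sst mice.

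Cabp2 lies on chromosome 19 of GRCm38, from base 4081578 to base 4087340. It had 0 reads in Ai14 mice of the Pvalb, Sst and Rbp4 comparisons and stood at 69.0 CPM with Ai162, 73.1 CPM with Ai148 in Rbp4 cells and 415.5 CPM with Ai148 in Sst cells, but at most at 2.03 CPM with Ai139 or Ai163.

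The pseudogenes Gm7743, Gm7308 and Gm14480, chosen after their values were seen, summed to between 639.8 and 1679 CPM in the 5 mice with GCaMP6 and to at most 47.4 CPM in all other sums. Gm7308 shares 177 of its 423 words of 25 bases with Calm2, a calmodulin gene, and Gm14480 shares 101 of 409. The transcripts used here do not hold Gm7743, the highest of the 3 in these mice, so its sequence was not compared. The ratio of their sum to the GCaMP6 level ran from 0.215 to 0.248 over the 5 mice, a spread of 1.154-fold beside 2.677-fold for GCaMP6 itself, so reads of the calmodulin part of GCaMP6 may have been counted for these genes. Since the sum was picked because it was high in these mice, this stays a hypothesis.

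Gm15459, a pseudogene sharing 1792 of 1917 words with the chaperone Hspa8, stood at 258 to 338 CPM in 7 TIGRE mice (5 with GCaMP6). The other 72 sums per mouse and class were at most 18.1 CPM. Gm15459 was chosen after its values were seen and no cause was tested.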
